A study of Mus musculus with 8 samples.

How the data were processed

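RNA was measured in vagal ganglia of wild-type mice given HDM or saline, with 4 libraries in each group. Per the labels, each library was made from a pool of 6 to 8 ganglia of 3 to 4 mice, so a replicate is a pool of animals and the spread between replicates holds both animal and preparation differences. Per the labels' protocols, RNA was purified from homogenised ganglia with a column kit, libraries were made with the stranded mRNA kit of Illumina, and they were sequenced on an Illumina NovaSeq instrument with paired reads of 50 bp. The labels also give a batch from 1 to 4 that equals the replicate number, so each batch holds 1 HDM and 1 saline pool.

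The deposited table holds counts, that is, whole numbers of reads or fragments per gene that are not normalised. Per the submitters' processing notes, the counts were made with featureCounts on the mouse genome GRCm38 (mm10). The aligner, the versions and the strand setting are not given in the sources used here. Each library is 1 column of counts, taken from 1 merged alignment file per the file headers, and columns were assigned to samples by the column names that the labels give. The table lists 55335 genes, of which 55154 had a symbol and were in GENCODE release M21, and 54899 had the same span there. Transcript GC content and gene overlaps come from that annotation. Since the strand setting is not given, reads of a gene and of an overlapping gene on the opposite strand may have been counted together. This concerns 31 of the 117 named genes, and 8 of the 24 named for their p in the group comparison. Reads that match several genes may have been dropped or shared, so members of near-identical families, such as the hemoglobin, Hspa1, Bex and Tceal genes and mitochondrial genes with nuclear copies, are uncertain.

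Library totals, in mega-counts (M), were 23.95 to 26.67 M counts in HDM and 26.87 to 31.28 M in saline. A count of 0 in a library allows up to 3 counts of its total, and this floor covers counting error only. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 17618 genes and removed 37717. Counts were scaled by TMM factors. HDM and saline were compared with edgeR's quasi-likelihood F-test (2-sided), with group as the only term, and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. Log2 fold changes are HDM over saline with a standard error (SE), and levels are CPM, counts scaled to a common library total with TMM factors, as mean ± SD. Biological variation between replicates within groups was fitted by the same model.

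The batch labels pair the libraries, so a fit with the replicate number as a block was run beside the main one, and its values are given where a call changed or a count moved by over 1.5 times. In the data, the deviations of same-numbered libraries from their group means correlated by −0.05 to 0.04 over genes, and 0 of the 8 libraries correlated best with its own number, so the pairing rests on the labels.

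Before the data were examined, 37 gene lists were fixed: responses to activity, glucocorticoids, cytokines, heat, hypoxia and injury, the clock and the cell cycle, genes of neurons, and markers of the cell types that a dissected ganglion could hold. The 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

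Genes were named by a rule written before the data were examined. It took the 12 higher and 12 lower called genes with the smallest p and 1 sign in all 4 batches, then 8 and 8 more by the same rule from the blocked fit, up to 4 members with the smallest p of each described list, and 13 genes of interest whatever their p. Symbols of predicted genes were counted and not named under this rule, and some genes that the rule took are not reported here. A few further genes were named after their values were seen, and the text says so.

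Alternatives listed beforehand were other size factors, 2 other filters, DESeq2 1.42.0, limma-voom, the block with and without a gene length correction, a threshold of 0.10, a 1.5-fold minimum, a robust dispersion, and leaving out each library or batch. After seeing the data, a correction for GC content was added: for each library, a natural spline with 4 degrees of freedom of log2 CPM on transcript GC, fitted on genes above a mean log2 CPM of 3, was used as an offset. Thinning of counts to the smallest library and leaving out saline 3 and saline 4 together were also added then. GC content was known for 99.9% of genes or more in each set checked.

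The fits were tested on simulated counts made from the real means, dispersions and library sizes, with 200 of 17436 tested genes changed in the comparison of HDM with saline. The group fit recovered 60.5% of them, with 7 false calls. It recovered 34.3% of the genes changed 1.25-fold, 65.7% of those changed 1.5-fold and 81.8% of those changed 2-fold. With the GC trends of the real libraries added to the simulation (17414 genes), false calls were 48 in the group fit and 12 after the GC correction. In the fit with the block, 58 of 172 calls were false with these trends and 12 of 135 without them. The added trends were made with the same spline that the correction removes, and changed genes were drawn without regard to GC content. These counts therefore cannot tell how the correction treats a real difference that follows GC content. A list of 20 genes changed 1.25-fold was found by camera, and 0 other lists were called. The simulated genes varied independently and without GC trends, whereas estimated correlations in the real lists reached 0.86 (sympathetic neuron markers). This simulation therefore cannot tell how often camera calls a list falsely when its members vary together.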

Results

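Vagal ganglia hold the cell bodies of the sensory neurons that the vagus nerve sends to the airways, the heart and the gut. Gene expression in these ganglia was compared between wild-type mice given HDM, the usual abbreviation of house dust mite, a common inhaled allergen, and mice given saline. Tissue was taken 1.5 h after challenge number 4. There were 4 pools of ganglia in each group, each from 3 to 4 mice. The HDM libraries held 23.95, 26.35, 25.01 and 26.67 M counts (replicates 1 to 4), and the saline libraries 26.87, 31.28, 29.30 and 31.23 M. The mean total was 25.5 ± 1.26 M in HDM and 29.7 ± 2.08 M in saline (SD, n = 4; exact permutation test, 2-sided, p = 0.0286, the smallest that 70 assignments can give, adjusted p = 0.04 over 7 library measures), and the HDM total was lower in 4 of 4 batches.

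The comparison asked which transcripts differ in vagal ganglia shortly after allergen exposure. Chgb and Chga, which encode granins, proteins of secretory granules, rose 1.34-fold and 1.22-fold in HDM, and Pcsk1n, which encodes an inhibitor of the prohormone convertase PC1, was 1.30-fold higher. Vgf, whose product is the precursor of several secreted peptides, was 1.40-fold higher. The myelin genes Pmp22 and Ugt8a fell, by 0.23 and 0.33 on the log2 scale. In all, 244 of 17618 tested genes differed, 216 of them higher and 28 lower in HDM (edgeR quasi-likelihood test, adjusted p under 0.05), and 243 of them had 1 sign in all 4 batches. Selection for a difference between the groups favours 1 sign, so this count is no separate support. With the replicate block, 713 genes differed, 531 higher and 182 lower, and these included all 244. The differences were small. The median fold was 1.20 among higher genes and 1.22 among lower ones, and 6 genes reached 1.5-fold. After a correction for GC content, added after the data were seen, 0 genes passed in edgeR (2044 at an unadjusted p under 0.05) and 0 in limma-voom. In edgeR 0 also passed without HDM 1, HDM 2 or saline 3 (2449, 2452 and 2373 at an unadjusted p under 0.05; limma-voom 0, 0 and 3), against 60 without HDM 4, 97 without saline 2 and 376 without HDM 3.

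Of the 12 higher genes with the smallest p, Chgb (ENSMUSG00000027350, GRCm38 chromosome 2, 132781278 to 132795079) had 88.4 ± 5.86 CPM in HDM and 65.9 ± 2.72 CPM in saline (n = 4 each; log2 fold change 0.42, SE 0.054, edgeR adjusted p = 0.00938). Pcsk1n (ENSMUSG00000039278, chromosome X, 7919822 to 7924410) had 224 ± 9.92 CPM and 172 ± 7.07 CPM (log2 fold change 0.38, SE 0.047, edgeR adjusted p = 0.00938). Vstm2l (ENSMUSG00000037843, chromosome 2, 157914653 to 157944719) had 56.9 ± 2.10 CPM and 43.4 ± 1.12 CPM (log2 fold change 0.39, SE 0.045, edgeR adjusted p = 0.00938), with all HDM libraries above 55 CPM and all saline libraries below 45 CPM. Ptms, which encodes parathymosin, rose by a log2 fold change of 0.32. Dlgap3 and Ppp1r9b, which encode scaffold proteins of the postsynaptic side, rose by 0.39 and 0.32, and Nrxn2, a presynaptic adhesion molecule, by 0.31. Myh14, a nonmuscle myosin heavy chain, rose by 0.43, and Palm3, Gipc1, Bex1 and Bex2 by 0.43, 0.32, 0.35 and 0.29. Their edgeR adjusted p lay between 0.00938 and 0.0159, and each was higher in HDM in 4 of 4 batches, which the naming rule required. After the GC correction their log2 fold changes lay between 0.17 and 0.37. Pcsk1n, Myh14, Nrxn2, Bex1 and Palm3 overlap an annotated gene on the opposite strand.

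**Figure D1:**
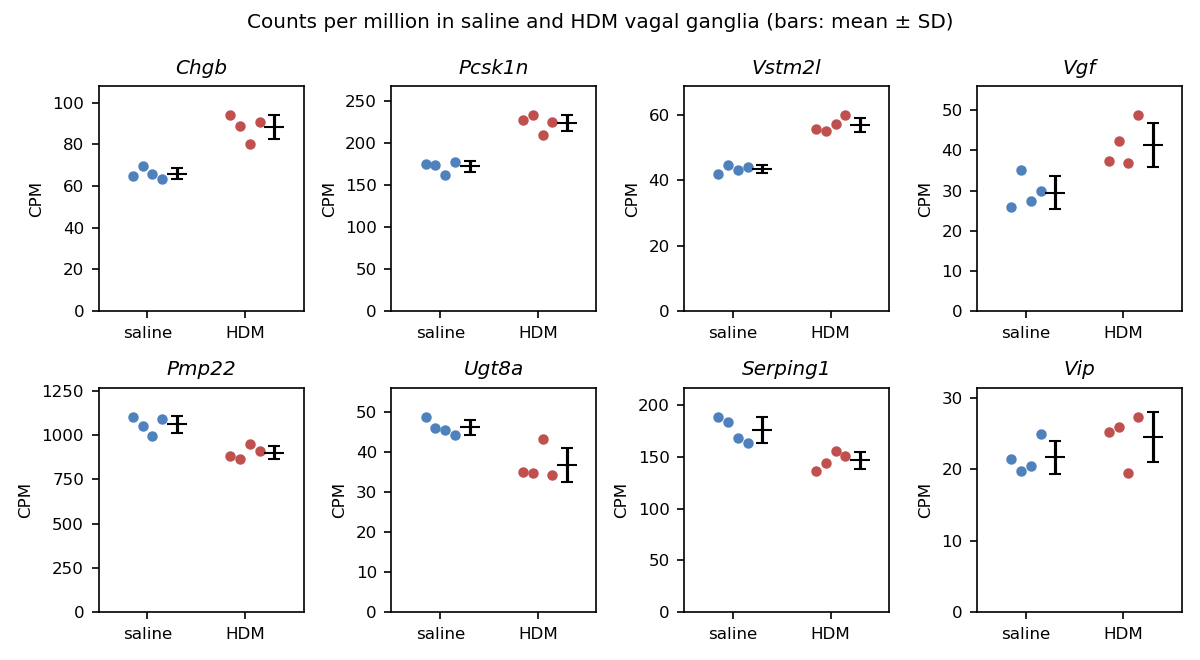
CPM (vertical axes, from 0) of 8 genes in each saline (blue) and HDM (red) library, with the mean and SD of 4 libraries beside the points. The HDM libraries lie above all saline libraries for Chgb, Pcsk1n and Vstm2l and below all of them for Pmp22, Ugt8a and Serping1, while the groups overlap for Vip.

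Among the lower genes, Pmp22 (ENSMUSG00000018217, chromosome 11, 63128982 to 63159547), which encodes a protein of compact peripheral myelin, had 901 ± 36.3 CPM in HDM and 1059 ± 47.9 CPM in saline (n = 4 each; log2 fold change −0.23, SE 0.048, edgeR adjusted p = 0.0336, and −0.27 with adjusted p = 0.0755 after the GC correction). Aspa, an aspartoacylase of myelin-forming cells, fell by a log2 fold change of −0.35. Ogn, a proteoglycan of connective tissue, fell by −0.44, and Serping1, the C1 inhibitor of the complement system, by −0.26. Snx5, Arhgap19, Cab39l, Stxbp6, Ctxn3, Med6, Zbtb37 and the pseudogene Tmem181b-ps were lower by log2 fold changes between −0.20 and −0.44. The block added Ntrk3, the receptor of neurotrophin-3 (log2 fold change −0.28, edgeR adjusted p = 0.0792 without and 0.00844 with the block), and Mrgprd, a receptor of itch- and pain-sensing skin neurons (−0.29, 0.164 without and 0.00904 with the block). It also added Nt5e, Tmem45b, Acpp, Smg1 and mt-Co1, all lower in HDM in 4 of 4 batches, which the naming rule required. Cd55, a complement regulator, was lower in both fits (log2 fold change −0.26). The higher genes that the block placed next were Fbxo2, Nudc, Edf1, Ccdc124, Sart1, Map7d1, Cygb and Fxr2, with log2 fold changes between 0.27 and 0.38, called in both fits.

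The title of the series concerns vagal neurons that express Vip, the gene of vasoactive intestinal peptide. Vip (ENSMUSG00000019772, chromosome 10, 5639218 to 5647617) had 24.5 ± 3.44 CPM in HDM and 21.7 ± 2.31 CPM in saline (log2 fold change 0.18, SE 0.10, edgeR adjusted p = 0.369), a difference within the spread between replicates, and was higher in HDM in 3 of 4 batches. Over the 27 alternatives its log2 fold change ran from 0.10 to 0.27, and it passed in none of them. Of 40 tested activity-regulated immediate early genes, 3 were higher and 0 lower over all genes, and 4 were higher when adjusted over the list alone. The 3 were Vgf, Junb (log2 fold change 0.45, edgeR adjusted p = 0.0173) and Jund (0.27, 0.0216). After the GC correction Vgf had 0.32, Junb 0.30 and Jund 0.091 (edgeR adjusted p = 0.244, 0.164 and 0.437). Junb and Jund encode subunits of the AP-1 transcription factor. The genes most used to mark recent neuronal firing did not pass: Fos had 4.65 ± 0.17 CPM in HDM and 5.05 ± 0.51 CPM in saline (log2 fold change −0.12, SE 0.11), and the values were −0.17 for Egr1, 0.20 for Npas4 and 0.06 for Arc. The list as a whole did not pass (camera adjusted p = 0.204, median log2 fold change 0.02). At this depth Fos, Egr1, Npas4 and Arc lay below 9 CPM on average, and only changes well above their SE could have been detected.

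Of the 18 neuropeptide genes tested, Chga and Vgf rose and 0 fell over all genes, and 4 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.503). Calca, the gene of calcitonin gene-related peptide, had a log2 fold change of −0.15, Tac1, the gene of substance P, −0.21, Cartpt 0.23 and Nts −0.38, and none of these passed. Of 32 vagal sensory receptors and channels, 0 passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.965). With the block 3 passed as higher, Crhr2, Ptgir and Cckar, and 2 as lower, Mrgprd and the opioid receptor Oprm1 (with block and GC correction Crhr2 went from 0.27 to 0.17, edgeR adjusted p = 0.265), and 6 were higher and 8 lower when adjusted over the list alone. The nociceptor channels Trpv1 and Trpa1 had log2 fold changes of 0.05 (SE 0.044) and −0.06 (SE 0.040), and P2ry1 and Npy2r, which mark airway and lung afferents, −0.08 and −0.01. Of 26 voltage-gated and leak channels, Cacna1h and Hcn2 rose (log2 fold changes 0.20 and 0.29), and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.919). After the GC correction Cacna1h had 0.072 and Hcn2 0.12 (edgeR adjusted p = 0.542 and 0.452). With the block Kcnh2 also passed as higher (log2 fold change 0.20, and 0.063 with block and GC correction, edgeR adjusted p = 0.682) and Kcna2 as lower, and 5 were higher and 6 lower when adjusted over the list alone. Of 21 cytokine receptors of sensory neurons, 0 passed over all genes and 1 was lower when adjusted over the list alone, or 0 with the block (camera adjusted p = 0.355). The receptors of interleukin-4 and interleukin-13 had log2 fold changes of 0.15 for Il4ra (edgeR adjusted p = 0.163) and −0.18 for Il13ra1 (edgeR adjusted p = 0.159), and Osmr had −0.19 and Cntfr 0.12. Over the alternatives Il4ra ran from 0.062 to 0.17 and Il13ra1 from −0.23 to −0.096.

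Of the 33 tested lists, 6 passed in camera with the preset correlation, 4 of them higher and 2 lower in HDM, and 9 passed with the block. With an estimated correlation 0 lists passed, and fry called 0. With block and GC correction 12 lists passed, among them synaptic vesicle genes (adjusted p = 0.0151) and interferon response genes (0.046) as higher and jugular neuron markers (0.0151), circadian clock genes (0.0151) and satellite glia markers (0.0208) as lower, and 0 passed in that setting with an estimated correlation (adjusted p = 0.875 for interferon response genes and 0.836 for the other 4). Synaptic vesicle genes were higher (18 tested, median log2 fold change 0.11, camera adjusted p = 0.0265, and adjusted p = 0.971 with an estimated correlation). Syp, a main membrane protein of synaptic vesicles, passed over all genes (log2 fold change 0.24), and 1 was higher when adjusted over the list alone, or 11 higher and 1 lower with the block. Cplx1 and Rab3a had 0.13 and 0.15 and Sv2b −0.18, below the threshold. The list did not pass without HDM 2 (adjusted p = 0.0595), HDM 4 (0.155), saline 1 (0.265) or saline 2 (0.0636), or after the GC correction described with the GC content (0.0865). That correction took the list's median log2 fold change to 0.046. Heat shock genes were higher as a list (15 tested, median 0.09, camera adjusted p = 0.0302, and adjusted p = 0.873 with an estimated correlation), with 0 members past the threshold over all genes and 3 adjusted over the list alone, or 1 and 7 with the block. Hspa1b and Hspa1a, 2 near-identical inducible Hsp70 genes, had log2 fold changes of 0.59 and 0.46, Bag3 0.20 (edgeR adjusted p = 0.119, and 0.0296 with the block, and 0.11 and 0.309 with block and GC correction) and Hsph1 0.18. This list did not pass without HDM 1 (0.0592), HDM 2 (0.129) or saline 1 (0.0622), or with the stricter filter of 1 CPM in 4 libraries (0.0502).

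**Figure D2:**
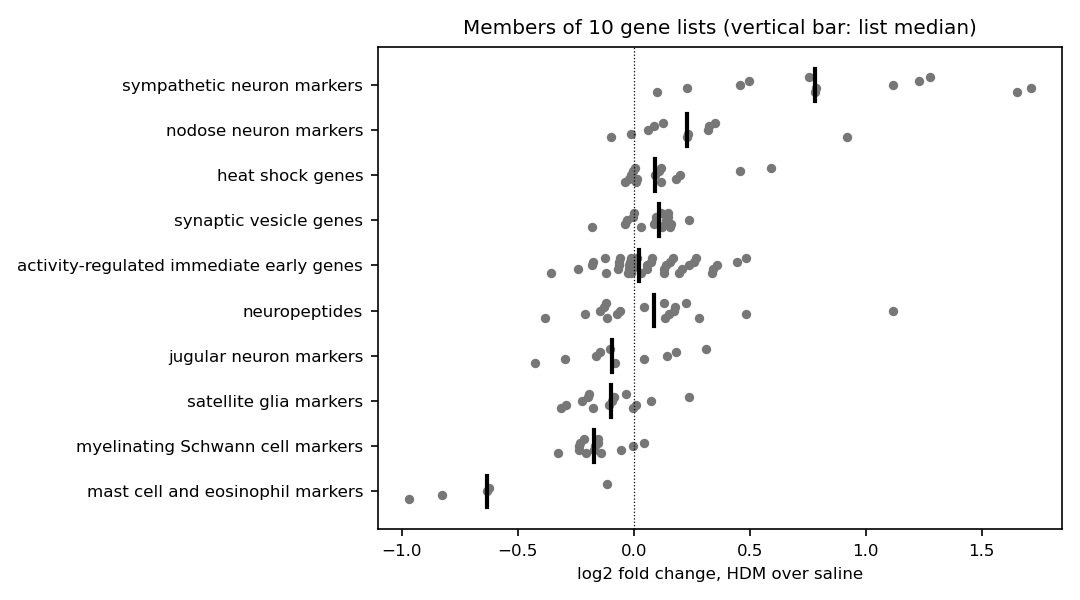
Log2 fold changes, HDM over saline (horizontal axis), of the tested members of 10 gene lists (1 point per gene), with a bar at each list's median. The medians run from −0.63 for mast cell and eosinophil markers to 0.78 for sympathetic neuron markers.

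In mice the vagal ganglia join a nodose and a jugular part, and markers of each were fixed as lists. Nodose neuron markers were higher as a list (11 tested, median log2 fold change 0.23, camera adjusted p = 0.0091, and adjusted p = 0.971 with an estimated correlation), with 0 past the threshold over all genes and 5 higher when adjusted over the list alone, or 4 and 6 with the block. Tbx3, a transcription factor, had a log2 fold change of 0.33 (edgeR adjusted p = 0.128, and 0.0348 with the block), Phox2a 0.92 and Cckar 0.24, and without HDM 4 Tbx3 had 0.22 and Phox2a 0.57. Sympathetic neurons also express Phox2a, which was at 13.4 CPM in HDM 4, where sympathetic markers were highest, and at 5.76 to 7.53 CPM in the other HDM libraries. The list did not pass without HDM 1 (0.0592), HDM 4 (0.0674) or saline 1 (0.0622). An exact permutation test of its mean log2 CPM gave p = 0.143 (2-sided, adjusted p = 0.583 over 17 marker lists), with HDM higher in 3 of 4 batches. Jugular neuron markers did not pass as a list (10 tested, median −0.09, camera adjusted p = 0.763), with 0 past the threshold over all genes, and 2 higher and 2 lower when adjusted over the list alone. With the block Tlx3 and Nefh passed as higher (log2 fold changes 0.31 and 0.18, and 0.14 and 0.066 with block and GC correction, edgeR adjusted p = 0.274 and 0.606) and Mrgprd as lower (−0.30, and −0.31 with block and GC correction, edgeR adjusted p = 0.0447), 3 were higher and 4 lower when adjusted over the list alone, and Mrgpra3 had −0.43 without passing.

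Myelinating Schwann cell markers were lower as a list (14 tested, 13 of them with a negative log2 fold change, median −0.17, camera adjusted p = 3.51e-05, and adjusted p = 0.873 with an estimated correlation). An exact permutation test of the list's mean log2 CPM gave p = 0.0857 (2-sided, adjusted p = 0.583 over 17 marker lists). The groups overlapped, with 6.72 in HDM 3 and 6.61 in saline 3, and HDM was higher in 1 of 4 batches. Pmp22 and Ugt8a passed over all genes, 4 were lower when adjusted over the list alone, and Drp2 passed with the block (log2 fold change −0.24). Mal had −0.17. Satellite glia markers did not pass as a list (14 tested, median −0.10, camera adjusted p = 0.0745). They passed as lower after the GC correction (adjusted p = 0.0292, and adjusted p = 0.654 with an estimated correlation). Over all genes 1 member was lower and 0 were higher, 1 was lower when adjusted over the list alone, or 1 higher and 1 lower with the block, and Apoe passed as higher with the block (log2 fold change 0.24, and 0.12 with block and GC correction, edgeR adjusted p = 0.241). Cdh19 and Slc1a3 had −0.18 and −0.20, and Slc1a3 ran from −0.26 to −0.060 without single libraries or batches. Mast cell and eosinophil markers were lower as a list (5 of 15 members tested, median −0.63, camera adjusted p = 0.0302, and adjusted p = 0.873 with an estimated correlation). An exact permutation test of the list's mean log2 CPM gave p = 0.0571 (2-sided, adjusted p = 0.583 over 17 marker lists). The tested members named here are mast cell genes, so the list says little about eosinophils. The members were close to the detection limit. Tpsb2, a mast cell tryptase, had 0.31 ± 0.054 CPM in HDM and 0.60 ± 0.13 CPM in saline, Cpa3, Hdc and Mcpt4 had log2 fold changes of −0.63, −0.63 and −0.83, and 0 passed over all genes and 1 was lower when adjusted over the list alone, or 0 with the block. The list did not pass without HDM 1 (0.0698), HDM 4 (0.0982), saline 1 (0.0622) or saline 2 (0.0634).

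Among genes of allergic and inflammatory responses, Junb alone passed over all genes. Of 16 type 2 cytokine and STAT6 response genes 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.919), with Arg1 at 0.55 (0.34 without HDM 4) and Crlf2 at 0.31. Of 15 NF-kB and acute inflammatory genes 0 passed either way (camera adjusted p = 0.516), with Ptgs2, Tnfaip3, Ccl2 and Nfkbiz at −0.85, −0.25, −0.32 and −0.17. Without saline 1 Ptgs2 had −0.086 and Nfkbiz −0.023. Of 24 glucocorticoid-induced genes 0 passed either way (camera adjusted p = 0.912), with Fkbp5 at 0.13, Zbtb16 at 0.16 and Cebpd at 0.34. Fkbp5 ran from 0.040 to 0.17 without single libraries or batches. Of 20 genes of the IL-6 family and STAT3 response Junb alone passed over all genes, and 1 was higher and 1 lower when adjusted over the list alone, or 3 and 1 with the block (camera adjusted p = 0.516), with Lcn2 at 1.39 (SE 0.65), a value that rested on HDM 1 and was 0.073 without it. Interferon response genes did not pass (19 tested, camera adjusted p = 0.428), and Irf7 was higher with the block (log2 fold change 0.49, edgeR adjusted p = 0.0499). Circadian clock genes did not pass as a list (camera adjusted p = 0.204), and Clock and Nr1d2 were lower with the block (log2 fold changes −0.18 and −0.16, edgeR adjusted p = 0.0348 and 0.0499, and −0.096 and −0.091 with block and GC correction, 0.253 and 0.32). Circadian clock genes passed as a lower list after the GC correction (adjusted p = 0.0292, and adjusted p = 0.85 with an estimated correlation). Without HDM 4 they also passed as lower (camera adjusted p = 0.0045), and without HDM 3 interferon response genes passed as higher (0.019). An estimated correlation was not run without single libraries. Of 16 axon injury genes 0 passed over all genes, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.446). With the block Gap43, a growth cone protein gene, was higher (log2 fold change 0.18, edgeR adjusted p = 0.0321), and 4 were higher and 2 lower when adjusted over the list alone. Irf7, Clock, Nr1d2 and Gap43 were named after their values were seen. Hypoxia-induced and cell cycle genes did not pass (camera adjusted p = 0.92 and 0.919). The median, the mean and the direction in camera did not share 1 sign in the lists of glucocorticoid-induced, type 2, hypoxia-induced, cell cycle, vagal receptor, voltage-gated channel, skeletal muscle and adipocyte genes. For glucocorticoid-induced genes the median was −0.01, the mean 0.07 and the direction in camera up.

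Sympathetic neuron markers showed the largest list median (12 tested, all with a positive log2 fold change, median 0.78, camera adjusted p = 1.99e-05, and adjusted p = 0.873 with an estimated correlation). None of the 12 passed over all genes, and 8 were higher when adjusted over the list alone, or 11 with the block. Hand2 and Hand1, transcription factors of sympathetic neurons, had log2 fold changes of 1.71 (SE 0.55) and 1.65 (SE 0.53), Gata2 0.78 and Ddc 0.50. Without HDM 4 the values were 1.04, 0.87, 0.47 and 0.28. The noradrenaline transporter gene Slc6a2, named after its values were seen, had 81.1, 81.4, 77.6 and 297 CPM in HDM 1 to 4 and 15.5, 109, 65.6 and 31.3 CPM in saline 1 to 4. The mean log2 CPM of the list was 4.88 ± 0.64 in HDM and 3.97 ± 0.65 in saline (n = 4 each; exact permutation test, 2-sided, p = 0.114, adjusted p = 0.583 over 17 marker lists), so the groups overlapped, and HDM was higher in 3 of 4 batches.

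With the block, mitochondrial protein-coding transcripts, fibroblast markers and erythroid markers also passed as lower lists (camera adjusted p = 0.0142, 0.0291 and 0.0291 with the block, and 0.0745, 0.091 and 0.296 without). With the block and an estimated correlation none of the 3 passed (adjusted p = 0.889, 0.959 and 0.889). An exact permutation test of their mean log2 CPM gave p = 0.486, 0.686 and 0.257 (2-sided, adjusted p = 0.795, 0.88 and 0.648 over 17 marker lists). HDM was higher in 1, 2 and 1 of 4 batches. Fibroblast and erythroid markers were highest in saline 1, at a mean log2 CPM of 5.21 and 5.10. The other saline libraries had 4.48 to 4.89 and 3.96 to 4.05. The share of counts from the 10 most abundant genes was 5.22 ± 0.27% in HDM and 5.78 ± 0.17% in saline, and 25205 ± 114 and 25652 ± 58.1 genes had a count (n = 4 each; exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.04 for each), both lower in HDM in 4 of 4 batches. The number of genes with a count was not adjusted for the library total, which was also lower in HDM. The share of counts from mitochondrial genes was 3.97 ± 0.26% in HDM and 4.52 ± 0.19% in saline (n = 4 each; exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.04). Among the mitochondrial transcripts mt-Co1, mt-Nd5 and mt-Nd4 had log2 fold changes of −0.21, −0.17 and −0.19, while mt-Nd6, which lies on the other strand, had 0.31. After the GC correction the median of the mitochondrial list went from −0.097 to −0.013, the direction in camera was up (adjusted p = 0.581, and 0.733 with the block), and mt-Co1 had −0.13. With block and GC correction mt-Nd6 was higher (log2 fold change 0.39, edgeR adjusted p = 0.0447), which it was not before the correction. In the 13 tested mitochondrial transcripts 2 were higher and 6 lower when adjusted over the list alone, and 6 were lower over all genes with the block. Of the 14 fibroblast genes 1 was lower when adjusted over the list alone, or 3 with the block, and of the 8 erythroid genes 1 was higher and 1 lower, or 1 and 5 with the block. Of the fibroblast genes, Mfap5 and Dcn passed as lower with the block (log2 fold changes −0.32 and −0.30, and −0.18 for Dcn without saline 1), and Lum and Cd34 had −0.17 and −0.12. Of the erythroid genes 1 passed as higher and 1 as lower over all genes with the block. The lower one was Hba-a1 (log2 fold change −1.09, and −0.45 without saline 1), and Hbb-bs had 133 CPM in saline 1 against 36.2 to 39.5 CPM in the other saline libraries.

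Pomc, the precursor gene of adrenocorticotropin and other pituitary peptides, was the called gene whose sign differed between batches. It had counts of 10, 6, 10 and 10 in HDM 1 to 4 and of 7, 72, 172 and 184 in saline 1 to 4 (log2 fold change −3.34, SE 0.69, edgeR adjusted p = 0.0345). Among the 6 genes that reached 1.5-fold, Pomc and Tceal5 (log2 fold change 0.60) had a symbol that is not of a predicted gene, and they and Gh were named after their values were seen. Between batches 1 gene differed, the growth hormone gene Gh (edgeR adjusted p = 0.00558), with 154 counts in HDM 2 and 1134 in saline 2 against 12 to 40 in the other HDM libraries and 15 to 107 in the other saline libraries. Gh was also lower in HDM with the block, in 4 of 4 batches (log2 fold change −1.77, edgeR adjusted p = 0.0203, and 0.0485 with block and GC correction), and did not pass without the block (−2.29, 0.269). In batch 1 Gh was nearly equal, at 0.544 CPM in HDM and 0.552 CPM in saline.

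**Figure D3:**
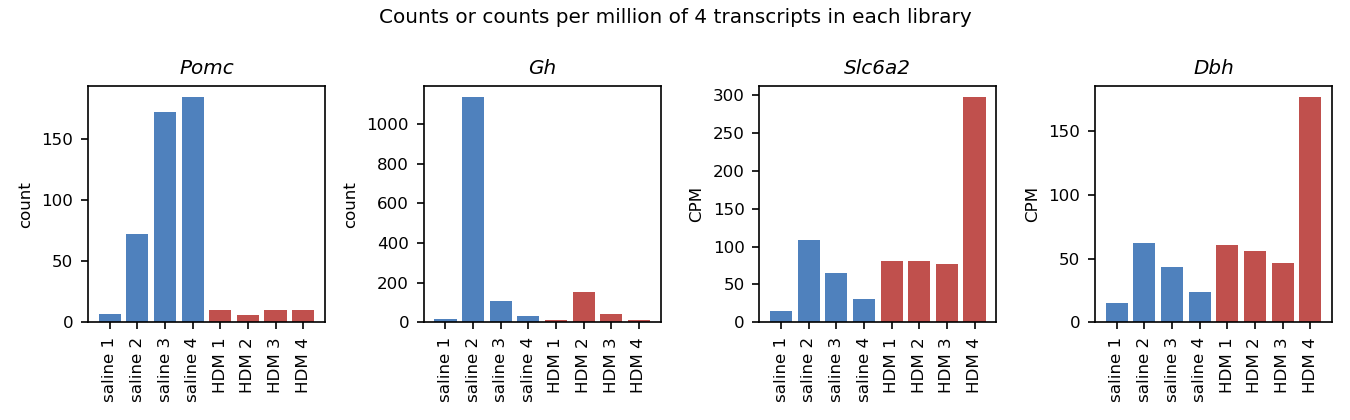
Counts of Pomc and Gh and CPM of Slc6a2 and Dbh (vertical axes, from 0) in each saline (blue) and HDM (red) library, 1 bar per library. Pomc is at 72 to 184 in saline 2, 3 and 4 and at 10 or below elsewhere, Gh reaches 1134 in saline 2, and Slc6a2 and Dbh are highest in HDM 4.

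The sign of a difference followed the GC content of the transcript. Higher genes such as Vstm2l (69.2% GC), Dlgap3 (64.5%) and Vgf (64.8%) were GC-rich and lower genes such as Ogn (36.3%), Aspa (39.7%) and Ugt8a (39.9%) were AT-rich, while Chgb (53.9%), Pmp22 (52.3%) and Serping1 (53.8%) lay between. The median GC content was 58.1% in the 216 higher genes, 43.3% in the 28 lower ones and 49.9% in all tested genes. Over 10954 genes the Spearman correlation of the log2 fold change with GC content was 0.59 (genes are not independent replicates). The slope of log2 CPM on GC content, per 10 points of GC, was 0.057, 0.052, 0.036 and 0.088 in HDM 1 to 4 and −0.012, −8.9e-05, −0.12 and −0.11 in saline 1 to 4 (exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.04), higher in HDM in 4 of 4 batches. When each library's GC trend was removed, 0 genes passed in edgeR (2044 at an unadjusted p under 0.05) and 0 in limma-voom (2006), and with the block 31 passed, 21 higher and 10 lower, of which 19 were among the 244. Among the 31, Chgb, Pcsk1n, Myh14, Edf1 and Sart1 were higher and Serping1, Ntrk3, Mrgprd and Nt5e lower (edgeR adjusted p = 0.0447 for each). Of the named genes that passed with the block and not without, Ntrk3, Mrgprd, Nt5e, Tmem45b and Gh were among the 31, and the others did not pass after this correction.

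**Figure D4:**
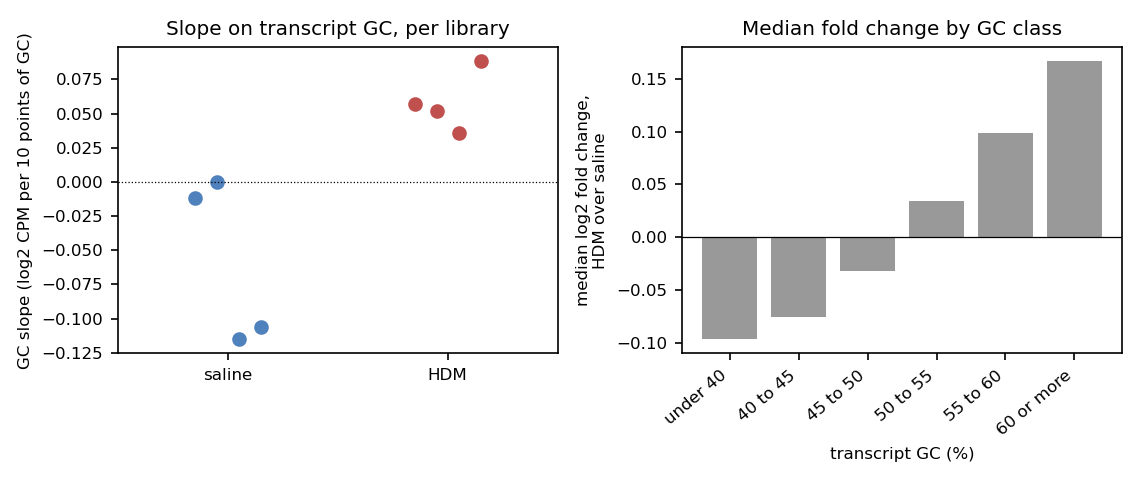
Left, the slope of log2 CPM on transcript GC content in each library (blue saline, red HDM). Right, the median log2 fold change, HDM over saline, of genes in 6 classes of GC content, which runs from −0.10 below 40% to 0.17 at 60% or more.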

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

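Tests of what lay behind the sympathetic markers were chosen after the result was seen. Among 282 groups of 4 libraries, 26 had 1 library far from the other 3, where chance alone gives about 14.1 (5%), so a single such library is often chance.

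Saline 1 stood out for red blood cell transcripts. Hba-a1 was at 69.66 CPM there against 20.1 to 21.8 in the other saline libraries, Hbb-bs at 132.8 CPM, Hbb-bt at 13.51 CPM, the share of hemoglobin counts at 0.02422% against 0.00712 to 0.00730%, and the mean log2 CPM of erythroid markers at 5.098. In the same library Ogn was at 159.1 CPM against 116 to 123, Ptgs2 at 1.915 CPM against 0.44 to 0.52, and the 10 most abundant genes took 6.028% of counts. Saline 4 stood out for Med6 (15.9 CPM), Syp (462.8 CPM), Cplx1 (519 CPM), Rab3a (268.1 CPM), Kcnh2 (72.01 CPM) and Tbx3 (82.36 CPM). Saline 3 stood out for Nt5e (52.16 CPM), and saline 2 for Il13ra1 (22.12 CPM) and Ddc (75.83 CPM). In HDM 3, Ugt8a was at 43.31 CPM against 34.24 to 34.98, Syp at 471 CPM and Cpa3 at 0.755 CPM. In HDM 1, Lcn2 was at 5.021 CPM against 0.38 to 1.06, and in HDM 4, Arg1 was at 10.31 CPM.

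HDM 4 stood out for sympathetic neuron markers. Gata2 was at 10.5 CPM, Hand2 at 22.39 CPM against 6.23 to 6.91, Hand1 at 9.552 CPM, and the mean log2 CPM of the list at 5.829 against 4.53 to 4.60. All 12 members were highest in HDM 4 among the HDM libraries and 9 were lowest in saline 1 among the saline libraries, which is consistent with differing amounts of sympathetic neurons in the pools, for example from the superior cervical ganglion, which lies near. A difference between the treatments also stays open and cannot be told apart from it with 4 pools per group, since the list mean gave p = 0.114 in an exact permutation test. Th, Ddc and Chrna3 are also expressed in vagal ganglia, where Chrna3 had 159 to 241 CPM in all 8 libraries.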

How the results depend on the processing

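The GC and thinning alternatives, the joint removal of saline 3 and saline 4, and the pairing of the GC correction with the block were chosen after seeing the data. The cause of a change was not tested unless stated. Limma-voom (214 genes), other size factors (195 and 170), a stricter filter (218) and thinning to the smallest library (213, of which 203 were among the 244) kept the count within 1.5 times. Upper-quartile factors gave 143 higher genes, and a robust dispersion gave 58 lower ones. DESeq2 called 871 genes (603 higher, 268 lower), no filter 722 (421 and 301), the block 713 (531 and 182), the block in DESeq2 765 (529 and 236), the block with a gene length correction 532 (392 and 140), and a threshold of 0.10 gave 709 (520 and 189). A minimum of 1.5-fold left 6 (3 and 3).

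The GC correction left 0 genes (0 higher, 0 lower). With the block it left 31 (21 and 10), and with a length correction as well 12 (8 and 4). Without saline 3 and saline 4 together, 0 genes passed (0 higher, 0 lower) in edgeR and 0 in limma-voom, with 2705 at an unadjusted p under 0.05 and fewer samples. Leaving out single libraries or batches gave 0 to 376 genes, 0 to 288 higher and 0 to 88 lower, the lowest without HDM 1, HDM 2, saline 3 or batch 2 (2357 at an unadjusted p under 0.05 and 0 in limma-voom without batch 2), and the highest without HDM 3. Without batch 1, 3 or 4, 5, 24 and 4 genes passed. The number of differing lists was 9 with the block, 12 with the block and GC correction, 13 without saline 3 and saline 4, 0 with an estimated correlation (smallest adjusted p = 0.873), 0 in fry (0.449), and 2 to 9 without single libraries (2 without saline 1). With the stricter filter or after thinning, mast cell and eosinophil markers had too few tested members for a test. The number of genes differing between batches was 130 in DESeq2 and 2 with the GC correction. Beyond the counts and genes given with the block in the comparisons above, the block changed no direction among the 117 named genes.

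No called gene among the named ones changed sign in any alternative. Of these 41 genes, 0 were still called without HDM 1, HDM 2 or saline 3. Most were named for having 1 sign in all 4 batches, which made a change of sign unlikely from the start. Of genes that did not pass, the log2 fold change of Arc was −0.058 with the GC correction, −0.056 with block and GC correction, −0.061 with block, GC and length correction, −0.14 without saline 3 and saline 4, and −0.060 to 0.16 without single libraries or batches. That of Trpa1 was 0.011, 0.011 and 0.0060 in the first 3 of these settings. That of Npy2r was 0.054, 0.054, 0.044 and 0.11 in the same 4 settings, 0.0013 after thinning and −0.092 to 0.056 without single libraries or batches. That of Cntfr was −0.0044 with block, GC and length correction, that of P2ry1 0.058 without saline 3 and saline 4, and that of Egr1 −0.43 to 0.095 without single libraries or batches. Depth limits the genes below about 1 CPM, such as the mast cell genes, and 34.3% of simulated genes with the smallest fold were recovered, so many small differences would be missed.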

Other observations

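The tests of GC content, depth, neuronal share and pituitary transcripts were chosen after the results were seen, as was the GC correction itself, while the counts over other splits of the libraries were planned before. Endothelial (camera adjusted p = 0.936), mural and smooth muscle (0.428), macrophage (0.455), skeletal muscle (0.919), adipocyte (0.992), cartilage (0.763), thyroid and parathyroid (0.856) and hindbrain and oligodendrocyte markers (0.763) did not pass. With the block 1 hindbrain and oligodendrocyte marker was lower when adjusted over the list alone, against 0 without. T and NK cell, B and plasma cell and neutrophil markers and sex-linked genes had fewer than 5 tested members and were not tested as lists, with 3, 3, 3 and 4 tested members and 0 of them past the threshold.

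Of the 35 splits of the 8 libraries into 4 and 4, 29 gave as many lists as the 6 of the real split, and the highest other split gave 17, so chance cannot be excluded for the number of lists and the samples hold structure that is not the group. For genes, 1 of the 35 splits, the real one, reached 244, and the highest other split gave 8. This is the smallest share that 35 splits can give. It argues against chance for the count when the pairs given by the batch labels are ignored, without excluding it. It does not argue against a technical measure that differs between the groups. Among the 8 splits that part every batch pair, the real one gave 713 genes with the block and the highest other 1, and 31 with block and GC correction and the highest other 0. These 8 splits are too few for a share under 0.05.

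Higher genes tended to be GC-rich and lower ones AT-rich. After thinning 203 calls remained, so the unequal number of counts by itself is argued against as the cause. Thinning removes counts alike from all genes of a library. It therefore cannot address a cause that changed both the totals and the GC trend. A GC-content trend between libraries is consistent with the 216 higher calls as a set, of which 0 were left in the group fit after correction, since their median log2 fold change went from 0.27 (25th to 75th percentile 0.22 to 0.31) to 0.17 (0.12 to 0.21) and their median SE from 0.050 to 0.047, with a smaller fold in 211, while in 5 (Tceal3, Mrpl57, Thrap3, Gm49227 and Hspd1-ps3, named after their values were seen) the fold grew, the unadjusted p fell and the call ended in the adjustment over all genes. All 216 higher calls kept a positive log2 fold change after the correction, so it shrank most of these differences without removing them. These genes were selected for being higher, which favours that sign. The GC slopes separated HDM from saline fully, so the correction takes out any group difference that follows GC content, whatever its cause. The loss of the calls therefore cannot tell a technical trend from an effect of HDM on GC-rich genes. Simulated counts with these trends gave 48 false calls in the group fit, higher and lower together, from genes that varied independently. For the 28 lower calls the trend cannot be told apart from another difference, since 0 were left but the median stayed within its earlier range, at −0.29 (−0.35 to −0.24) before and −0.25 (−0.31 to −0.18) after, with a median SE of 0.060 and 0.055, and in 4 (Pmp22, Serping1, Gtf3c2 and Pomc, the last 2 named after their values were seen) the fold grew and the unadjusted p fell. Nor can it be told apart for the 19 of the 244 calls that remained with block and correction: they kept a median 0.864 of their log2 fold change (0.585 to 1.21), and the 17 higher ones had a median of 0.27 (median SE 0.041), but they are the genes selected for passing, all 31 calls of that fit had an adjusted p between 0.0447 and 0.0485, 5 of the 244 remained with a length correction as well, and 25 of 144 calls were false in simulated counts with such trends. A larger share of neurons cannot be told apart either, since the lists went different ways. Neuronal list genes went both ways after the correction (75th percentile 0.077, median −0.00076, bootstrap 95% interval of the median over genes −0.034 to 0.027). Before the correction, the 45 neuronal genes below the median GC had a median log2 fold change of −0.080. The 70 at or above it had 0.096, so these genes did not rise together. Myelinating Schwann cell and satellite glia markers were lower after the correction (camera adjusted p = 1.49e-10 and 0.0292) and nodose neuron markers higher (0.000333). None of these 3 passed with an estimated correlation (adjusted p = 0.654, 0.654 and 0.85). Jugular neuron markers went down after the correction without passing (camera adjusted p = 0.0934). An effect of HDM itself stays open.

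Gh and Prl transcripts, which belong to the pituitary, varied together over the 8 libraries (Pearson r = 0.93, exact permutation p = 0.00198, Spearman rho = 0.881, exact permutation p = 0.00724, 1 relation tested), but without saline 2 and HDM 2 r was 0.665 (exact permutation p = 0.154), so the relation rests on these 2 libraries and 1 outside source of both cannot be told apart from others. A source that brings Gh and Pomc in a fixed mix is argued against, since the ratio of Pomc to Gh counts ran from 0.039 to 6.13 between the libraries, a 157-fold range, against a 6.22-fold range for Prl to Gh. Corticotroph or melanotroph cells in some pools cannot be told apart from other sources, since the markers Tbx19 and Pax7 had 20 counts over all 8 libraries, and a difference due to HDM in the vagal ganglia stays open.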
